A study of Mus musculus with 18 samples.

How the data were processed

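RNA sequencing of 18 samples was deposited as 2 gene tables with 9 samples each, for the siRNA knockdowns and for the 4-OHT deletions. Per the labels, total RNA was extracted with Trizol from Braf/Pten mouse melanoma cells in culture, and stranded poly-A libraries (dUTP) were made from 500 ng. Per the submitters' processing notes, the tools were bcl2fastq 2.17.1.14, cutadapt 1.10, Bowtie2 2.2.8 and 2.1.0, TopHat2 2.0.10, HTSeq and DESeq2, with the mm9 genome. The notes do not state the role of each Bowtie2 version, the strand setting of the counting, the annotation release or any filter.

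The count values are raw reads per gene as the authors deposited them, counted with HTSeq per the submitters' processing notes. The signal values are the authors' normalized counts, and the deposited numbers equal the counts divided by a size factor per sample. A second deposited signal is the same divided by the median transcript length of the gene. The log2 values are the authors' deposited log2 fold changes of their comparisons, made with DESeq2 per the submitters' processing notes. The p-values were deposited by the authors with these log2 fold changes, raw and adjusted, and only the deposited lists of changed genes were compared with the calls made here. All other results come from the raw counts. Gene symbols, Ensembl identifiers and mm9 coordinates are those of the tables, and no coordinate of another build was mixed in.

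The knockdown table lists 22285 genes, and 23181 are in that of the deletions. Total counts (in units of 1e6) were 23.7, 26.5 and 25.2 for siC, 23.7, 23.1 and 23.1 for siMitf and 21.2, 26.9 and 27.6 for siSox10. They were 31.6, 26.0 and 30.7 for WT, 26.2, 27.5 and 47.1 for Smarca4, and 28.3, 28.6 and 32.7 for Bptf. The chi-square per degree of freedom between replicates ran from 3.32 to 12.42 in the knockdown table and from 1.61 to 29.51 in the deletion table; counting error alone gives 1. The highest values were those of WT-2 against WT-1 (29.51) and WT-3 (29.35), whereas WT-1 against WT-3 gave 5.17. The lowest were those between Bptf libraries (1.61, 1.75 and 1.88) and of Smarca4-1 against Smarca4-2 (1.78). Smarca4-3 gave 8.02 against Smarca4-1 and 8.92 against Smarca4-2. The labels do not say whether libraries this close came from separate cultures. Without WT-2, 5257 genes were higher and 5221 lower in Smarca4 libraries, and 4847 and 4968 in Bptf libraries. The mitochondrial share of counts was 2.14 to 2.28% in WT and 1.05 to 1.27% in the other deletion groups, and 0.493 to 0.66% in the knockdown table.

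Each table was analysed separately, since batch and table cannot be told apart. Genes were kept by filterByExpr, which left 14033 and 14585 genes with 99.95 and 99.96% of the counts. Counts were scaled by TMM (factors 0.952 to 1.03 in the knockdown table and 0.936 to 1.093 in the deletion table) and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with all 3 groups of a table fitted together. The biological coefficient of variation was 6.97% and 7.03%. P-values were adjusted by Benjamini-Hochberg over all tested genes of a comparison, and a gene was called at an adjusted p under 0.05 with no minimum fold. TMM and library totals both fix only relative amounts, so a change of total RNA per cell cannot be seen. CPM values are TMM-scaled, and fold changes of groups with 1 to 3 counts are given as 95% counting intervals, and those with 0 counts as bounds from a floor of 3 counts over the group. These intervals and bounds cover counting error only.

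The genes named are drawn from a rule fixed before the data were examined. It takes the 4 targeted genes, 15 lineage and state genes in every comparison, in comparisons with a control the 6 largest changes per direction among called genes with at least 5 CPM and non-overlapping groups, up to 4 called members of each gene list with at least 1 CPM, and 6 shared genes per direction of an overlap. The sex-linked genes beyond those of the rule were chosen after the values were seen. Fixed at the same time were 31 gene lists of the melanocyte lineage, cell states, stress and metabolism, remodelling complexes and other cell types. A list was tested where at least 3 members were tested, with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the lists of a comparison. Where the calls of a list are counted, the count is over all genes and, where it differs, also adjusted over the list alone. A list counts as called by camera with the preset correlation.

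Comparisons that share a control were set against 20 simulations of unchanged groups with the same controls, because 3 controls cannot be divided between them. Overlaps of knockdown and deletion calls were tested with Fisher's exact test among 13694 genes (16 tests, Benjamini-Hochberg). Also fixed before the data were examined were the alternatives: RLE size factors or library totals for scaling, no count filter or a mean count of at least 50, a replicate block, only the 2 compared groups in the fit, DESeq2 1.42.0, stricter thresholds and leaving out each library in turn. A test against a fold of 1.5 and autosomes only were added after the data were seen. Other tools were data.table (version 1.17.8), numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

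The pipeline was tested on simulated data with the depth and spread of the tables. In the siMitf comparison, 40, 78, 96 and 100% of 50 genes each changed 1.25, 1.5, 2 and 4-fold were called with the right sign, and 6% of calls were unchanged genes. In the Smarca4 comparison the shares were 36, 94, 98 and 100%, again of 50 genes per fold, and 4.1% of calls were unchanged genes. With no gene changed, edgeR called 0 and 1 genes. Camera called the raised list in both tables and 0 of 60 unchanged lists. Genes were drawn independently in these simulations, so they do not test camera on lists of correlated genes. The cell cycle list with siMitf, for example, had an estimated correlation of 0.539.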

Results

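Poly-A RNA of in vitro cultured Braf/Pten mouse melanoma cells was sequenced in 18 samples, which fall into 6 groups of 3. The knockdown table holds cells given control siRNA (siC), siRNA against Mitf (siMitf) or siRNA against Sox10 (siSox10). The deletion table holds cells labelled by the gene that was floxed, with 4-hydroxytamoxifen (4-OHT) used for the deletion. Its groups are a control (WT), Smarca4, which encodes the chromatin remodeller Brg1, and Bptf, which encodes the largest subunit of the remodelling complex NURF. Total counts per sample ran from 21.2 to 27.6 (in units of 1e6) in the knockdown table and from 26.0 to 47.1 in the deletion table, where Smarca4-3 was the deepest. The labels do not say whether the 3 samples of a group came from separate cultures or animals, so the p-values measure only the spread between these samples. The source is given as a mouse tumour for cells described as cultured, and the deletion table carries the word tumours in its description. In the text, ± after a mean is the SD of 3 samples, and ± after a log2 fold change is its standard error. A value marked -fold is a linear ratio without a sign, not a log2 fold change.

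The siRNA groups address which transcripts change when Mitf, the transcription factor that drives the melanocyte lineage, or Sox10, a neural crest and glial transcription factor, is reduced. Mitf (ENSMUSG00000035158, mm9 chromosome 6, 97757052 to 97971352) stood at 15.3 ± 0.789 counts per 1e6 counts (CPM) with siC and 5.29 ± 0.852 CPM with siMitf. Its log2 fold change was -1.53 ± 0.11 (edgeR adjusted p = 5.86e-08). With siSox10 it was higher than with siC, at 21.7 ± 1.32 CPM (log2 fold change 0.50 ± 0.10, adjusted p = 0.000825). Sox10 (ENSMUSG00000033006, chromosome 15, 78985343 to 78994920) fell from 28.8 ± 3.62 to 4.22 ± 1.95 CPM with siSox10 (log2 fold change -2.81 ± 0.19, adjusted p = 6.05e-09). With siMitf it stood at 20.8 ± 1.40 CPM (log2 fold change -0.47 ± 0.16, adjusted p = 0.0354). That call for Sox10 with siMitf was lost under several alternatives, among them library totals only (0.0717), DESeq2 (0.24), and without siC replicate 2 (0.152), siC replicate 3 (0.0545), siMitf replicate 1 (0.102) or siMitf replicate 2 (0.116). Smarca4 and Bptf did not pass with siMitf (0.16 and -0.11, adjusted p = 0.0803 and adjusted p = 0.294) or siSox10 (0.14 and 0.02, adjusted p = 0.104 and adjusted p = 0.875). With library totals only, Smarca4 passed as higher with siMitf (0.24, adjusted p = 0.00748) and siSox10 (0.24, adjusted p = 0.00637), and without siMitf replicate 3 it passed with siMitf (adjusted p = 0.0455).

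**Figure D1:**
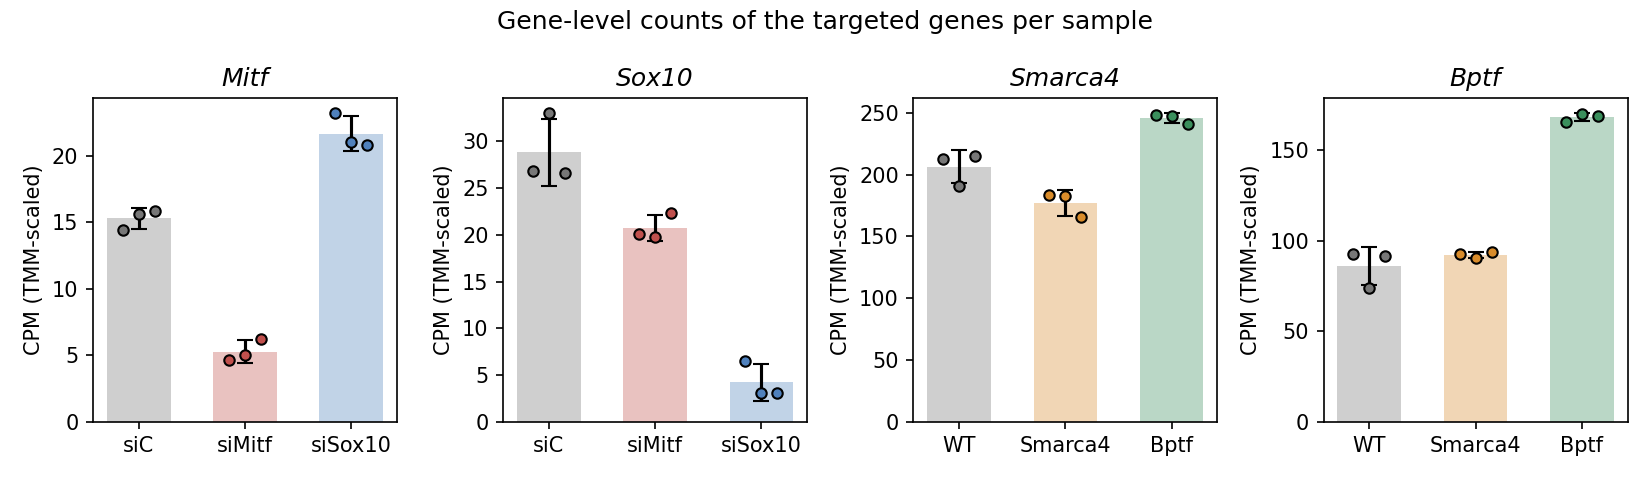
TMM-scaled CPM of the 4 targeted genes in each sample (points), with the mean (bar) and SD (error bar) of 3 samples per group. Mitf stood at 5.29 CPM with siMitf against 15.3 with siC, Sox10 at 4.22 with siSox10 against 28.8, and Bptf at 168 in the libraries labelled Bptf against 86.2 in WT.

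With siMitf, smooth muscle and pericyte genes fell as a list, called also at adjusted p = 0.0454 with an estimated correlation. Cell cycle genes rose in 34 of 38 cases and glial genes fell in 10 of 18, in lists whose calls were lost at adjusted p = 0.287 and adjusted p = 0.106 with an estimated correlation. Il1rl1, an interleukin receptor, rose from 38.9 ± 1.18 to 313 ± 66.8 CPM (log2 fold change 3.01 ± 0.12, adjusted p = 1.41e-10). The plasminogen activator inhibitor Serpinb2 rose from 2.39 ± 0.0574 to 35.2 ± 5.19 CPM, a log2 fold change of 3.88 ± 0.12 with an adjusted p of 5.25e-12. The proliferin gene Prl2c3 (3.67), the glutathione transferase Gsta4 (2.13), the repressor Bcl6b (2.01) and the chromatin protein Hmga1 (1.89) also rose (log2 fold changes). Gfra3, a receptor of the GDNF family, fell from 18.2 ± 0.710 to 2.25 ± 0.357 CPM (log2 fold change -3.02 ± 0.13, adjusted p = 3.36e-10). Kank4 (-2.97), the G protein regulator Rgs8 (-2.53), the secreted factor C1qtnf3 (-2.47), Scel (-2.25) and the sodium channel Scn7a (-2.18) fell as well.

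Among lineage genes, the neural crest factors Sox6 (log2 fold change -1.20), Foxd3 (4.02 to 2.01 CPM) and Tfap2b (-0.72) fell with siMitf, while the nerve growth factor receptor Ngfr rose (0.55 ± 0.10, adjusted p = 0.000854). Of 23 melanocyte and neural crest regulators tested, 2 rose and 6 fell, and the list as a whole was not called (camera adjusted p = 0.259). Sox9, a neural crest factor, rose by a log2 fold change of 0.40 (adjusted p = 0.00998), a call lost without siC replicate 3 (0.0571) or siMitf replicate 2 (0.052). The differences for Erbb3 (0.08), Ednrb (0.07), Pax3 (-0.12), Pmel (0.40), Axl (0.14) and Cdkn1a (-0.07, or 0.02 with library totals only) did not pass the test. Axl, a receptor kinase of invasive melanoma, passed it with library totals only (0.23, adjusted p = 0.0114) and without siMitf replicate 3 (0.19, 0.0457). The count filter left out 6 of the genes to be named. The pigment enzyme genes had fewer counts with both siRNAs than with siC: over siC, siMitf and siSox10, Tyr had 9, 2 and 0, Tyrp1 6, 1 and 0, and Dct 14, 1 and 1. In the edgeR fit with no count filter, siMitf against siC gave adjusted p 0.386, 0.436 and 0.0583 for Tyr, Tyrp1 and Dct. With siSox10, Tyr (adjusted p = 0.0378) and Dct (0.0359) passed as lower in that fit, and Tyrp1 (0.113) did not, while 12 of the 14 counts of Dct came from siC-2. Mlana, Kit and Zeb1 had at most 12 counts in a group and did not pass in that fit. In both tables the Zeb1 counts are those of the identifier ENSMUSG00000093585. Reads assigned to any other identifier are not in them, so they do not show that Zeb1 was absent. In the pigmentation list, 2 of 12 tested members rose, among them the melanosome glycoprotein Gpnmb (0.56) and Rab32 (0.41), while the melanosome transport gene Mlph fell (-0.84). Neither this list (camera adjusted p = 0.259) nor that of Mitf targets outside pigmentation (0.644, 4 higher and 2 lower of 19, or 5 and 3 adjusted over the list alone, median -0.04 and mean 0.04, with a median of 0.05 with library totals only) was called.

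Of 38 cell cycle genes tested with siMitf, 34 rose and none fell (35 rose adjusted over the list alone), with a median log2 fold change of 0.74. Camera gave this list an adjusted p of 7.9e-20, and adjusted p = 0.287 with an estimated correlation. The replication licensing factor Cdc6 (1.13), the mitotic kinases Aurkb (1.05) and Bub1 (1.03) and the anaphase activator Cdc20 (1.03) were among them, and the proliferation marker Mki67 rose from 48.9 ± 10.6 to 76.6 ± 6.99 CPM (0.65 ± 0.11). Lysosome genes rose in 16 of 29 cases (17 adjusted over the list alone), including the galactosidase Gla (0.90) and the proton pump subunit Atp6v0d2 (0.54). Their camera adjusted p was 9.1e-07 and adjusted p = 0.395 with an estimated correlation. MAPK output genes rose in 10 of 20 cases and fell in 2 (10 and 3 adjusted over the list alone). The phosphatases Dusp5 (1.52) and Dusp4 (0.81) and the immediate early gene Egr1 (1.13) rose, and the ephrin receptor Epha4 fell (-0.86). The list had adjusted p = 0.000644 and adjusted p = 0.13 with an estimated correlation.

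Interferon response genes rose with siMitf in 12 of 23 cases and fell in 1 (14 and 1 adjusted over the list alone; Ifi44 2.14-fold, Isg15 1.05 in log2 fold change). Class I antigen presentation genes rose in 8 of 14 (11 adjusted over the list alone), including the transactivator Nlrc5 (0.75) and the immunoproteasome subunit Psmb8 (0.49). Camera adjusted p was 0.00126 for each of these lists. Both calls were lost with an estimated correlation, at adjusted p = 0.579 for interferon genes and adjusted p = 0.395 for class I genes. Secreted inflammatory factors rose in 11 of 26 cases and fell in 7 (13 and 7 adjusted over the list alone): the cytokine Csf2 (2.69), the growth factor Hgf (1.26) and the protease Mmp10 (2.15-fold) rose, and Il6 fell (-0.89). Their camera adjusted p was 0.0283, with adjusted p = 0.353 with an estimated correlation. Macrophage and myeloid markers rose in 8 of 26 cases (9 adjusted over the list alone), such as Cd68 (49.3 to 72.1 CPM) and Itgax (12.0 to 17.4 CPM). This list had adjusted p = 0.00648 and adjusted p = 0.395 with an estimated correlation.

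Smooth muscle and pericyte genes fell with siMitf in 9 of 12 cases (10 adjusted over the list alone), and this list was called with a preset correlation (adjusted p = 6.83e-15) and with an estimated correlation (adjusted p = 0.0454). The actin Acta2 went from 7088 ± 514 to 3724 ± 223 CPM, and the myosin Myh11 (-1.59), the calponin Cnn1 (-1.32) and the kinase Mylk (-0.93) fell. Glial and Schwann cell genes fell in 10 of 18 cases and rose in 1 (11 and 2 adjusted over the list alone), including the myelin genes Mal (-4.22) and Pmp2 (-3.84) and the adhesion molecule L1cam (-1.69). Camera gave them adjusted p = 6.3e-10 and adjusted p = 0.106 with an estimated correlation. Invasive-state melanoma genes fell in 14 of 29 cases and rose in 7. The matricellular gene Ctgf went from 4045 ± 55.4 to 1977 ± 137 CPM, while the AP-1 factor Fosl1 rose (0.78). As a list they had adjusted p = 0.0108 and adjusted p = 0.13 with an estimated correlation.

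In total, 1682 genes were higher and 1704 lower with siMitf than with siC among 14033 tested (edgeR), and 219 and 210 of them changed over 2-fold. The 3 samples of each group did not overlap in 39.7% of genes, where chance gives 10%. Scaling matters for the balance: 49.7% of called genes were higher with TMM and 72.4% with library totals only. The latter called 2909 higher and 1109 lower. Of the other lists, none was called: hypoxia and glycolysis (adjusted p = 0.644), oxidative phosphorylation (0.395), integrated stress response (0.195, 1 higher and 10 lower of 22, or 2 and 11 adjusted over the list alone), p53 targets (0.144), unfolded protein response (0.127), cholesterol synthesis (0.482), BAF and PBAF complex (0.98), NURF and ISWI complexes (0.65), T and NK cell (0.51), endothelial (0.395), fibroblast (0.644), keratinocyte and epidermis (0.978), hair follicle (0.76), adipocyte (0.65) and skeletal muscle (0.0888). The unfolded protein response and skeletal muscle lists were called with library totals only, at adjusted p 0.0289 (higher) and 0.0256 (lower). Median, mean and test differed in sign for the BAF and PBAF, keratinocyte and hair follicle lists.

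With siSox10, glial genes and smooth muscle and pericyte genes fell as lists, each called also at adjusted p = 0.0365 with an estimated correlation. Ngfr fell from 26.7 ± 0.885 to 5.45 ± 1.33 CPM (log2 fold change -2.31 ± 0.12, adjusted p = 4.33e-10), and Erbb3, a neuregulin receptor, from 17.3 ± 2.08 to 3.42 ± 0.356 CPM (-2.35 ± 0.14, adjusted p = 1.65e-09). Gfra3 fell from 18.2 to 0.275 ± 0.0568 CPM (-6.05), and Kank4 (-5.95), Rgs8 (-5.15), Slc35f1 (-3.91), Mlph (-3.39) and the myelin gene Plp1 (-3.20) also fell. Increases included the pentraxin Nptx1 (4.67), Serpinb2 (4.46), Prl2c3 (4.13), Cd34 (3.73), Il1rl1 (3.46, to 428 ± 30.0 CPM) and Hmga2, an architectural chromatin protein that rose from 41.3 ± 8.10 to 231 ± 19.6 CPM (2.49 ± 0.12, adjusted p = 1.4e-10).

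Melanocyte and neural crest regulators fell in 11 of 23 cases and rose in 3 with siSox10, with Foxd3 (-3.51), Sox6 (-3.06) and Tfap2b (-2.40) falling. Their camera adjusted p was 1.92e-05, with adjusted p = 0.297 with an estimated correlation. Sox9 (0.69), Axl (0.24) and Mki67 (0.84) rose. Pax3 fell by 0.99 on the log2 scale (adjusted p = 0.0489), and this call was lost when any of the 9 libraries was left out, at adjusted p from 0.0603 without siMitf replicate 3 to 0.151 without siC replicate 1. Pmel (0.22), Ednrb (0.24) and Cdkn1a (-0.08, or 0.02 with library totals only) did not pass the test. Pigmentation genes rose in 4 of 12 cases and fell in 1 (Gpnmb 0.97, the motor protein Myo5a 0.47), a list not called (adjusted p = 0.269, median 0.22 and mean -0.05). Mitf targets outside pigmentation rose in 8 of 19 cases (9 adjusted over the list alone) and fell in 3, with the GTPase Rragd (1.61) and the phosphatase Acp5 (0.99) higher and the repressor Tbx2 lower (-1.52), and were not called (adjusted p = 0.211).

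Glial and Schwann cell genes fell in 14 of 18 cases with siSox10 and rose in 1 (15 and 2 adjusted over the list alone), with a median log2 fold change of -1.80 and Pmp2 (-4.50), Mal (-3.82), Plp1 (-3.20) and L1cam (-3.14) among them. Smooth muscle and pericyte genes fell in 11 of 12, including the proteoglycan gene Cspg4 (-1.40), Cnn1 (-1.50), Myh11 (-1.33) and Acta2 (-1.26). These lists were called at adjusted p 4.93e-16 and 2.8e-15, and both held with an estimated correlation (adjusted p = 0.0365 each). Cell cycle genes rose in 33 of 38 cases and fell in 1 (35 and 1 adjusted over the list alone), with Bub1 (1.15), Aurkb (2.15-fold) and the kinetochore gene Cenpf (1.05) among them (adjusted p = 4.93e-16, and adjusted p = 0.297 with an estimated correlation). Lysosome genes rose in 21 of 29 (Gla 1.35, Atp6v0d2 1.31, the protease Ctsd 0.59; adjusted p = 5.21e-09, and adjusted p = 0.297 with an estimated correlation).

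Secreted inflammatory factors rose in 16 of 26 cases with siSox10 and fell in 6 (17 and 7 adjusted over the list alone). Csf2 (3.29), Mmp10 (2.47) and the growth factor Areg (1.53) rose, and Il6 fell by a log2 fold change of -1.56. MAPK output genes rose in 11 of 20 and fell in 4, with Dusp5 (2.14), Dusp4 (1.35) and Egr1 (1.31) rising. Both lists had adjusted p = 0.000816, and adjusted p = 0.147 with an estimated correlation. Class I antigen presentation genes rose in 10 of 14 (11 adjusted over the list alone; Nlrc5 1.06, H2-K1 0.53; adjusted p = 0.00105, and adjusted p = 0.324 with an estimated correlation). Interferon genes rose in 15 of 23 and fell in 2 (16 and 2 adjusted over the list alone), with a wide spread between siSox10 samples: the chemokine Cxcl10 stood at 3.25 ± 2.70 CPM against 0.301 ± 0.118. The interferon list had adjusted p = 0.0077 (and adjusted p = 0.679 with an estimated correlation). Macrophage and myeloid markers rose in 12 of 26 cases and fell in 3 (Itgax 1.22, Cd68 0.76, Laptm5 0.72; adjusted p = 0.00264, and adjusted p = 0.324 with an estimated correlation). Invasive-state genes fell in 11 of 29 and rose in 7 (12 and 8 adjusted over the list alone). Thbs1, which encodes a thrombospondin, went from 27220 ± 2090 to 13520 ± 266 CPM and Fosl1 rose (0.88). This list (median -0.09, adjusted p = 0.0243, and adjusted p = 0.147 with an estimated correlation) was not called with library totals only (median 0, adjusted p = 0.056). Integrated stress response genes fell in 13 of 22 cases and rose in 3 (14 and 3 adjusted over the list alone), with the pseudokinase Trib3 (-0.78) and the folate enzyme Mthfd2 (-0.74) lower and the cystine transporter Slc7a11 higher (1.97). Their adjusted p was 0.0285, with adjusted p = 0.324 with an estimated correlation and 0.056 with library totals only.

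In all, 2375 genes were higher and 2341 lower with siSox10 (394 and 439 over 2-fold), and the groups did not overlap in 45.8% of genes against 10% by chance. With library totals only, 70.5% of called genes were higher against 50.4% with TMM, and 3768 genes were called higher. The lists not called were hypoxia and glycolysis (adjusted p = 0.644), oxidative phosphorylation (0.644), p53 targets (0.843), unfolded protein response (0.0961, and called higher with library totals only at 0.0275), cholesterol synthesis (0.332), BAF and PBAF complex (0.737), NURF and ISWI complexes (0.737), T and NK cell (0.656), endothelial (0.244), fibroblast (0.194, 7 higher and 12 lower of 26, or 7 and 13 adjusted over the list alone), keratinocyte and epidermis (0.919), hair follicle (0.56), adipocyte (0.919) and skeletal muscle (0.244). Median, mean and test differed in sign for p53 targets and for the keratinocyte and adipocyte lists.

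The responses to the 2 siRNAs were then compared gene by gene. Of the 1682 genes higher with siMitf, 1362 (81%) were also higher with siSox10, against 285 for independent sets. Of the 1704 lower, 1271 (74.6%) were also lower, against 284, and 11 and 6 genes went opposite ways. The balance of shared genes depends on scaling: with library totals only, 2364 were higher and 828 lower with both siRNAs. Serpinb2, Prl2c3, Il1rl1, Gsta4, Bcl6b and Hmga1 were among the shared increases, and Gfra3, Kank4, Rgs8, C1qtnf3, Scel and Sh2d4a among the shared decreases. The same siC samples serve both comparisons, and part of the excess may come from them. Unchanged groups set against shared controls in 20 simulations gave a correlation of the log2 fold changes across genes of 0.50 against the observed 0.82, and a covariance of 0.0174 against 0.194, a difference of 0.177. Genes are not independent replicates in these figures.

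**Figure D2:**
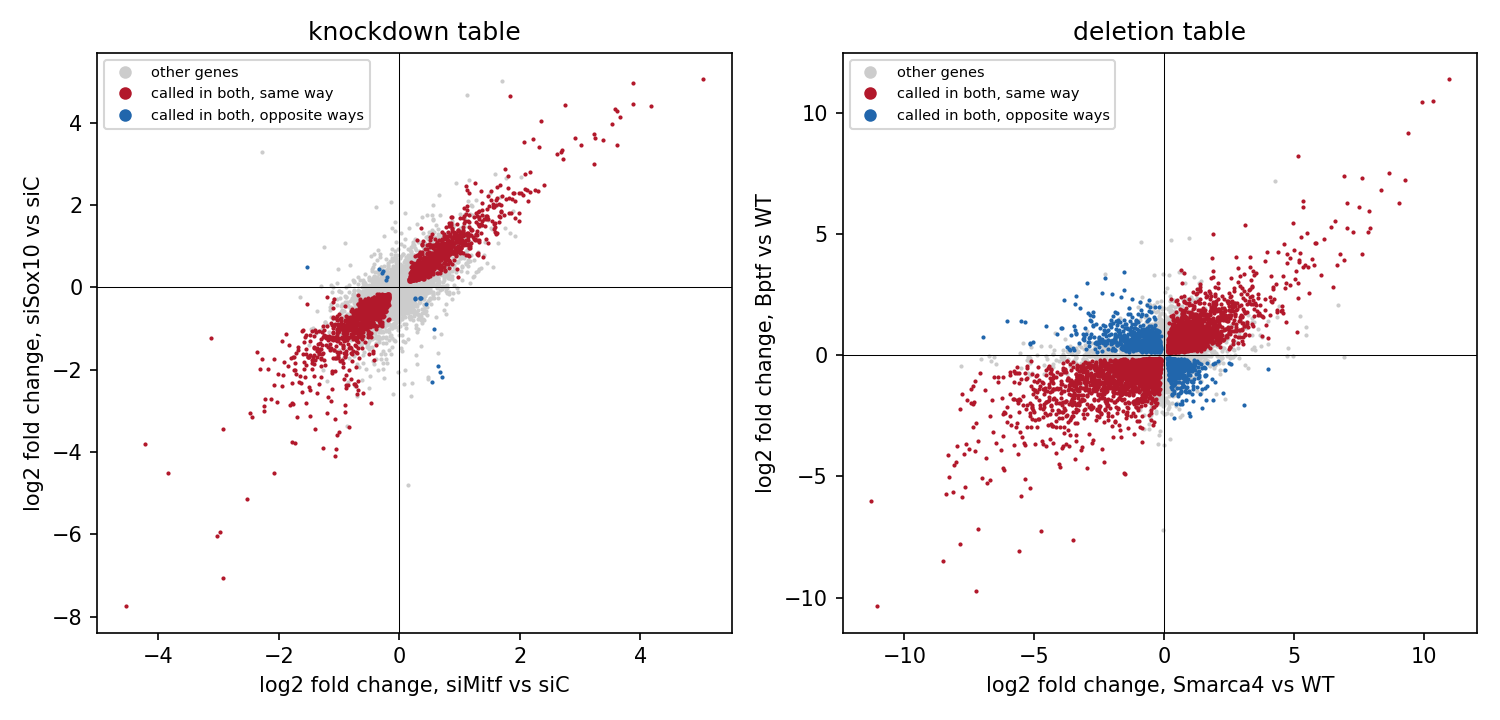
Log2 fold change of each tested gene in the pairs of comparisons that share a control, siMitf against siSox10 (left) and Smarca4 against Bptf (right); points are genes, coloured by whether they were called in both. In the left panel 11 and 6 of the genes called with siMitf were called the opposite way with siSox10, and in the right panel 797 and 930 of those called in Smarca4 libraries were called the opposite way in Bptf libraries.

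Tested directly, siSox10 and siMitf differed in 529 genes higher and 620 lower with siSox10 (33 and 103 over 2-fold; groups apart in 24.6% of genes, 10% by chance). Ngfr stood at 5.45 ± 1.33 CPM with siSox10 and 39.0 ± 2.30 with siMitf (log2 fold change -2.85 ± 0.12, adjusted p = 2.54e-10). Erbb3 (-2.43), Foxd3 (-2.51), Mlph (-2.55) and Plp1 (-2.14) were lower with siSox10. Sox10 was lower (-2.34) and Mitf higher (2.03). Smarca4 (-0.02), Bptf (0.13), Axl (0.10), Ednrb (0.16), Pax3 (-0.88), Pmel (-0.17), Cdkn1a (-0.01) and Mki67 (0.19) did not pass, nor did Sox9 (0.29, adjusted p = 0.086), which passed without siC replicate 2 (adjusted p = 0.039). With no count filter, none of Tyr, Tyrp1, Dct, Mlana, Kit and Zeb1 passed by edgeR (adjusted p from 0.602 to 1). Melanocyte regulators (8 of 23 lower, 1 higher, or 8 and 2 adjusted over the list alone) and glial genes (7 of 18 lower, 9 adjusted over the list alone) were called lower at adjusted p 1.02e-09 and 3.68e-09, each with adjusted p = 0.25 with an estimated correlation. Fibroblast genes (8 of 26 lower; 11 lower and 1 higher adjusted over the list alone; adjusted p = 0.000534, and adjusted p = 0.604 with an estimated correlation) and smooth muscle genes (3 of 12, such as Cspg4 at 31.3 against 62.6 CPM; 0.00476, and adjusted p = 0.345 with an estimated correlation) were lower. Cholesterol synthesis (6 of 24 higher, 9 adjusted over the list alone; Hsd17b7 0.39; adjusted p = 0.00137, and adjusted p = 0.345 with an estimated correlation) and lysosome genes (4 of 29, 5 adjusted over the list alone; 0.00137, and adjusted p = 0.731 with an estimated correlation) were higher. So were p53 targets (5 of 24, 7 adjusted over the list alone; Pmaip1 0.62; 0.00476, and adjusted p = 0.25 with an estimated correlation) and inflammatory factors (7 of 26 with 2 lower, 8 and 3 adjusted over the list alone; Mmp10 1.36, Areg 1.24; 0.00476, and adjusted p = 0.28 with an estimated correlation). No cell cycle gene differed (0 of 38, camera adjusted p = 0.203), by edgeR in a comparison where 3022 genes had an unadjusted p under 0.05. These totals depend on single libraries: without siSox10 replicate 2 they were 215 higher and 250 lower, without siMitf replicate 2 323 were higher, and without siMitf replicate 1 404 were lower.

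The deletion table addresses, per the series title, whether Brg1 and Bptf are needed for normal gene expression in these melanoma cells. The label names the floxed gene, but the gene-level counts of that gene did not drop to a low level. Smarca4 (ENSMUSG00000032187, chromosome 9, 21420613 to 21508674) stood at 206 ± 13.3 CPM in WT, 177 ± 10.2 in libraries labelled Smarca4 (log2 fold change -0.22 ± 0.06, adjusted p = 0.00555) and 246 ± 3.93 in libraries labelled Bptf (0.25, adjusted p = 0.00253). The first of these differences was not called with library totals only (-0.02, adjusted p = 0.812). Bptf (ENSMUSG00000040481, chromosome 11, 106894395 to 106993441) stood at 86.2 ± 10.6 CPM in WT, 92.5 ± 1.64 in Smarca4 libraries (0.10, adjusted p = 0.252; called with library totals only at 0.31 and 0.00167) and 168 ± 2.21 in Bptf libraries (0.96 ± 0.08, adjusted p = 1.28e-07). A count over a whole gene cannot isolate the floxed part, and the labels do not say which exons were floxed.

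The WT libraries differ from the others in sex-linked transcripts. Xist, the noncoding RNA of the inactive X chromosome (ENSMUSG00000086503, chromosome X, 100655714 to 100678556), stood at 468 ± 89.1 CPM in WT, 0.201 ± 0.0814 in Smarca4 libraries and 0.364 ± 0.192 in Bptf libraries. The Y-linked helicase gene Ddx3y had 5 counts over the 3 WT samples against 83.0 ± 8.18 and 91.7 ± 4.37 CPM, and Eif2s3y had 13 counts against 106 ± 9.51 and 90.5 ± 0.553 CPM. Kdm5d had 1 count and Uty 2 counts in WT. In Smarca4 libraries the ratio to WT was between 473 and 104000 for Kdm5d and between 317 and 9470 for Uty (95% counting intervals), and in Bptf libraries between 634 and 140000 and between 450 and 13500. All 9 knockdown libraries had Y-linked counts, with Ddx3y at 96.9 to 113 CPM in group means. In the deletion table, the labelled gene and the sex-linked transcripts divide WT from the other samples alike. A comparison with WT therefore holds the deletion and any other difference between these cells, which cannot be told apart. Higher, lower, increase and decrease describe differences between groups there.

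**Figure D3:**
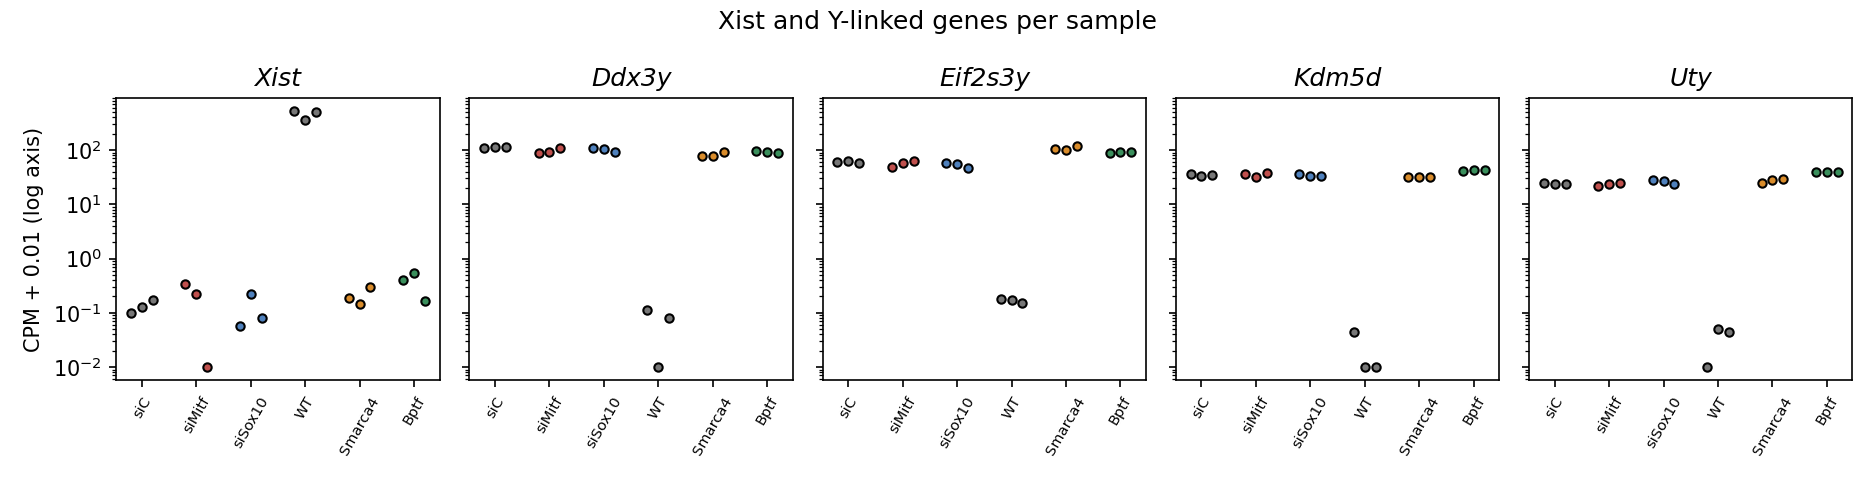
CPM plus 0.01 (log axis) of Xist and 4 Y-linked genes in each of the 18 samples, grouped as labelled. Xist stood at 468 CPM on average in WT and under 0.4 in the other groups, and Ddx3y at 83.0 and 91.7 CPM in Smarca4 and Bptf libraries against 5 counts in the 3 WT samples.

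Between Smarca4 libraries and WT, smooth muscle and interferon genes were lower and sterol synthesis genes higher, as lists called also with an estimated correlation (adjusted p = 0.0325, adjusted p = 0.0215 and adjusted p = 0.00304). Thbs1 (ENSMUSG00000040152, chromosome 2, 117937612 to 117952869) stood at 223 ± 5.60 CPM against 10530 ± 1475 (log2 fold change -5.56 ± 0.10, adjusted p = 1.54e-14), and Ctgf at 72.2 ± 0.310 against 4405 ± 75.6 (-5.93 ± 0.06, adjusted p = 1.28e-16). Apart from Xist, decreases included the complement gene C1qc, the cornified envelope gene Scel (-7.79), the natriuretic peptide receptor Npr3 (451 ± 22.6 to 2.33 ± 0.219 CPM), the deiodinase Dio3 (-7.10) and the cytokine Tnfsf15 (-6.99). C1qc had 3 counts in Smarca4 libraries against 874, a ratio between 131 and 1870. Among increases besides the Y-linked genes, Cyp1a1, a xenobiotic-metabolising enzyme, had 3 counts in WT and a ratio between 123 and 1750. The X-linked gene Mtap7d2 was higher by a log2 fold change of 6.41.

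Smooth muscle and pericyte genes were lower in 11 of 13 cases and higher in 1 in Smarca4 libraries, with a median log2 fold change of -2.50. Acta2 stood at 374 ± 14.4 CPM against 6600 ± 326, and Mylk (-5.21), Lmod1 (-5.18) and Cnn1 (-4.32) were lower (adjusted p = 9.74e-17, and adjusted p = 0.0325 with an estimated correlation). Interferon response genes were lower in 22 of 25 cases and higher in none, with a median of -2.83: the antiviral enzyme Oas2 (-5.59), Ifi44 (-4.36), Ifit1 (-4.29) and the regulator Irf7 (-4.20; list adjusted p = 1.63e-22, and adjusted p = 0.0215 with an estimated correlation). Cholesterol synthesis genes were higher in 23 of 24 and lower in none (Insig1 2.97, Pcsk9 2.90, Dhcr24 2.08, Mvd 1.96; adjusted p = 5e-15, and adjusted p = 0.00304 with an estimated correlation). Class I antigen presentation genes were lower in 12 of 14 (13 adjusted over the list alone), including Psmb8 (-2.16), the peptide transporter Tap2 (-1.29), H2-D1 (-1.23) and B2m (-1.05). Their adjusted p was 0.000255, with adjusted p = 0.16 with an estimated correlation.

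Macrophage and myeloid markers were lower in 24 of 26 cases, with a median of -3.65 (adjusted p = 3.15e-13, and adjusted p = 0.0969 with an estimated correlation). The complement gene C1qa had no count in Smarca4 libraries and 820 in WT, at least 361-fold lower (floor of 3 counts over the group), C1qb had 3 against 703 (ratio 105 to 1500), and the arginase Arg1 was lower by a log2 fold change of -7.33. Fibroblast genes were lower in 19 of 25 and higher in 4, with the collagen gene Col3a1 at 794 ± 7.67 against 7393 ± 361 CPM, Lum (-3.58), Mfap5 (-2.62) and Lox (-2.44). The fibroblast list had adjusted p = 4.09e-10, and adjusted p = 0.0783 with an estimated correlation. Invasive-state genes were lower in 21 of 29 and higher in 7, with Il6 (-6.14) and Cyr61 (-3.98) beside Ctgf and Thbs1 (adjusted p = 2.65e-09, and adjusted p = 0.126 with an estimated correlation). Hypoxia and glycolysis genes were lower in 16 of 26 and higher in 3 (the peptide hormone Adm -2.53, the collagen hydroxylase P4ha2 -1.55; adjusted p = 0.0097, and adjusted p = 0.196 with an estimated correlation). In the same libraries, the mitochondrial share of counts was 1.05 to 1.27%, against 2.14 to 2.28% in WT, and Xist and Y-linked genes moved with all of these groups. Counts of whole samples cannot tell lower expression within melanoma cells from fewer cells of other types. This holds for every comparison of the deletion table.

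Sox10 stood at 172 ± 14.3 CPM in Smarca4 libraries against 82.4 ± 9.20 in WT (log2 fold change 1.06 ± 0.08, edgeR adjusted p = 4.31e-08). Mitf stood at 13.9 ± 1.40 against 8.32 ± 0.158 (0.75 ± 0.10, adjusted p = 1.28e-05). Ngfr (ENSMUSG00000000120, chromosome 11, 95430132 to 95449049) stood at 277 ± 18.6 against 97.2 ± 14.8 (1.51 ± 0.09, adjusted p = 3.73e-09). Ednrb (2.05), Pax3 (1.81), Sox9 (0.99), Erbb3 (0.46), the cell cycle inhibitor Cdkn1a (0.55) and Mlana (2.34, at 68 counts against 10) were higher. Axl was lower (-0.23, adjusted p = 0.00338; -0.03 and 0.684 with library totals only). Mki67 was lower (-0.26, adjusted p = 0.0236). This call was lost with library totals only (0.605), with only the 2 groups in the fit (0.0503) and without Smarca4 replicate 1 (0.0741), Smarca4 replicate 2 (0.0699) or WT replicate 1 (0.131). Pmel (-0.24) and Kit (0.87) did not pass, although Kit passed without WT replicate 2 (1.31, adjusted p = 0.0374). The count filter left out Tyr, Tyrp1, Dct and Zeb1. Tyr had 43 counts in Smarca4 libraries, 11 in WT and 5 in Bptf libraries. In the fit with no count filter it passed as higher in Smarca4 libraries than in WT (1.53, adjusted p = 0.0293) and did not pass between Bptf libraries and WT (adjusted p = 0.333). Tyrp1, Dct and Zeb1 had at most 4 counts in a group.

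Pigmentation genes were higher in 9 of 14 cases and lower in 1 in Smarca4 libraries, with Gpnmb (ENSMUSG00000029816) at 573 ± 22.6 against 81.9 ± 4.58 CPM, the melanocortin receptor Mc1r (2.39) and Myo5a (1.24). The list was called at adjusted p = 0.0165, with adjusted p = 0.163 with an estimated correlation. Mitf targets outside pigmentation were higher in 12 of 22 and lower in 5 (Rragd 4.99, the desaturase Scd2 1.92, the receptor Met 1.69; adjusted p = 0.0267, and adjusted p = 0.163 with an estimated correlation). Melanocyte and neural crest regulators were higher in 16 of 23 and lower in 4 (Lef1 2.16, Id3 -1.94, Snai2 -1.87) but not called (adjusted p = 0.087). Glial genes were lower in 11 of 19 and higher in 6 (Scn7a -3.66, Mal -3.61, Gfap -3.60; adjusted p = 0.00981, and adjusted p = 0.0991 with an estimated correlation). Lysosome genes were higher in 25 of 29 and lower in 2 (Gla 2.50, Npc1 1.68, Neu1 1.52, Ctss -4.05; adjusted p = 1.37e-05, and adjusted p = 0.163 with an estimated correlation). Integrated stress response genes were higher in 13 of 22 and lower in 6, with Slc7a11 (4.35), the stress factor Atf3 (4.01), Ddit3 (1.66) and Chac1 (1.62) higher. They were called at adjusted p = 5.96e-05, with adjusted p = 0.16 with an estimated correlation. MAPK output genes were higher in 16 of 20 and lower in 3 (Fosl1 2.94, Egr1 2.68, Dusp4 2.37, Spry1 -2.96; adjusted p = 2.11e-06, and adjusted p = 0.16 with an estimated correlation).

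**Figure D4:**
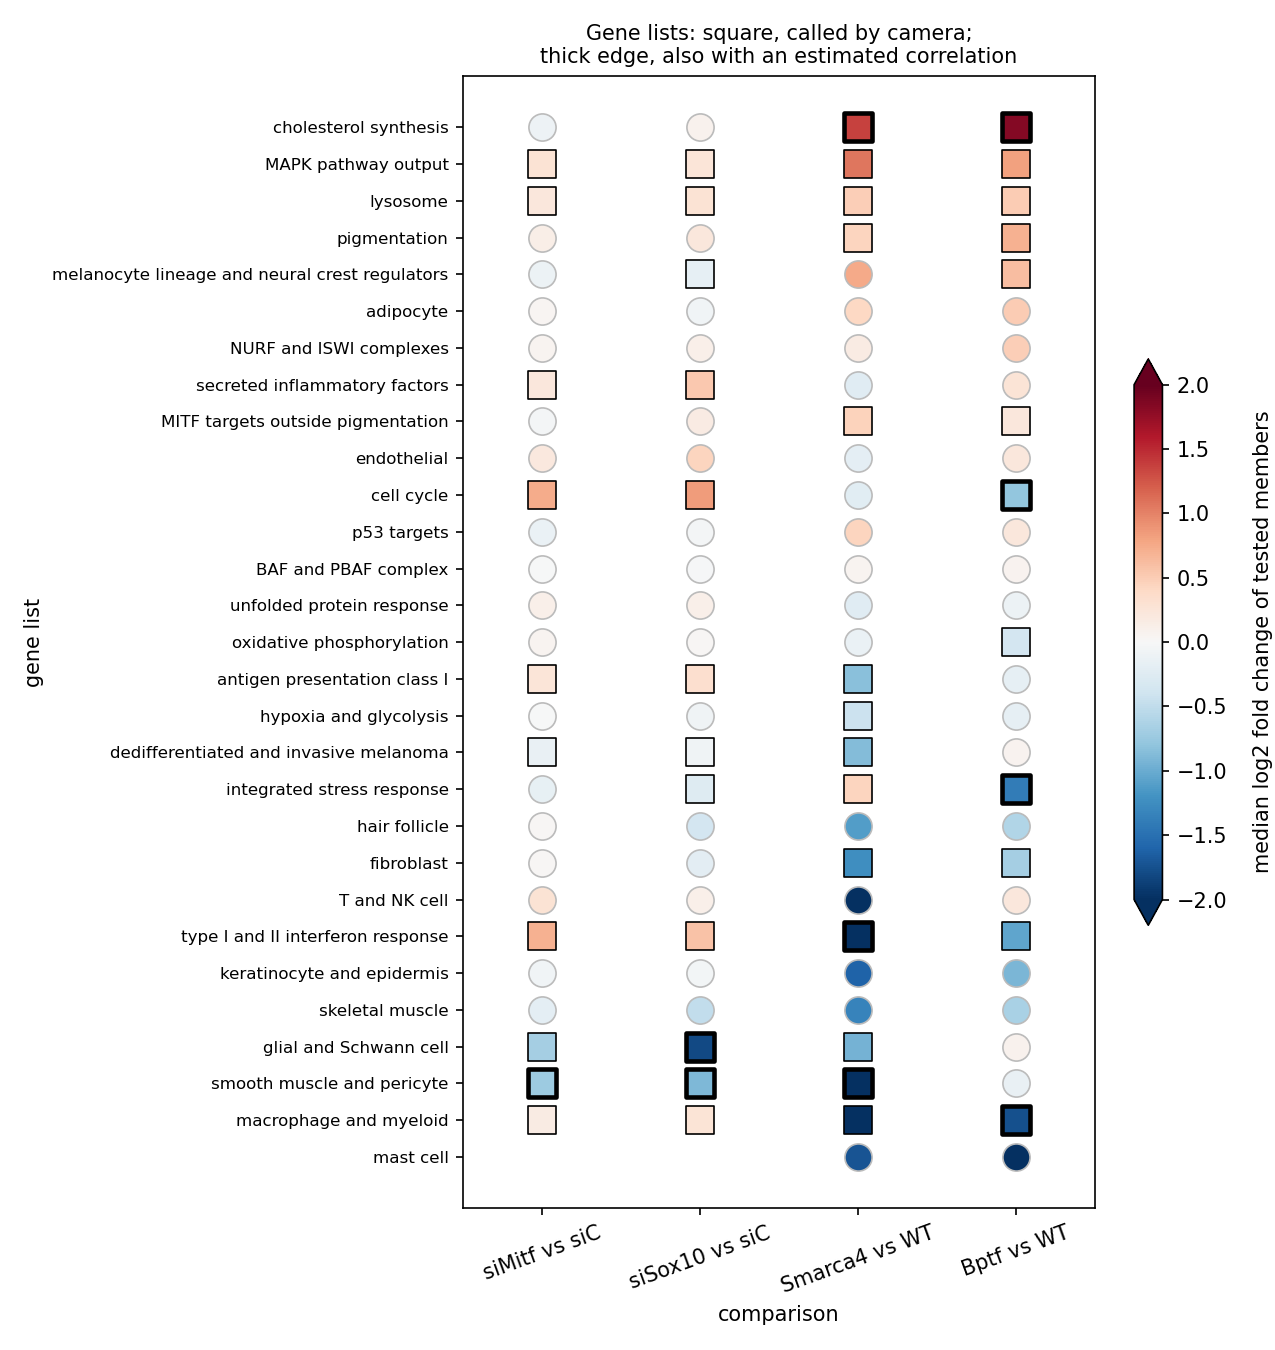
Median log2 fold change of the tested members of each gene list (colour) in the 4 comparisons with a control; squares are lists called by camera with a preset correlation, and thick edges those also called with an estimated correlation. Cholesterol synthesis had medians of 1.36 and 1.83 in Smarca4 and Bptf libraries, and cell cycle genes 0.74 and 0.85 with siMitf and siSox10 against -0.79 in Bptf libraries.

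In all, 4850 genes were higher and 4934 lower in Smarca4 libraries than in WT among 14585 tested (67.1%), with 1278 and 2040 over 2-fold and groups apart in 67.7% of genes against 10% by chance. With library totals only, the median of all genes shifted by 0.205, and 6842 genes were called higher and 3576 lower. Of called genes, 65.7% were then higher against 49.6% with TMM. The lists not called were cell cycle (adjusted p = 0.409, 5 higher and 19 lower of 38, with Cdt1 at 2.52 and Rrm1 at -1.74), p53 targets (0.0924, 15 higher and 5 lower of 24, with Gdf15 at 4.01), secreted inflammatory factors (0.997, median -0.24 and mean 0.04), oxidative phosphorylation (0.784), unfolded protein response (0.464), BAF and PBAF complex (0.628), NURF and ISWI complexes (0.463), T and NK cell (0.351), mast cell (0.584), endothelial (0.94), keratinocyte and epidermis (0.16), hair follicle (0.282), adipocyte (0.61, median 0.41 and mean -0.07) and skeletal muscle (0.112).

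Between Bptf libraries and WT, sterol synthesis genes were higher, and integrated stress response, cell cycle and myeloid genes lower. All 4 lists were called also with an estimated correlation (adjusted p from 9.34e-05 to 0.0104). Dhcr24, a reductase of cholesterol synthesis (ENSMUSG00000034926, chromosome 4, 106233643 to 106261718), stood at 400 ± 3.88 CPM against 59.0 ± 5.99 (log2 fold change 2.76 ± 0.07, adjusted p = 2.24e-12). Cdkn1c, a cell cycle inhibitor, stood at 4.04 ± 0.421 against 227 ± 14.3 (-5.81 ± 0.09, adjusted p = 2.69e-14). Besides Xist and the Y-linked genes, C1qa (-6.02), C1qc (-5.73), the cochlin gene Coch (-4.86) and Igfbp2 (-3.89) were among the decreases, and the reductase Akr1c18 (6.10) and the peptidase Ecel1 (5.45) among the increases.

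All 24 cholesterol synthesis genes were higher in Bptf libraries, with a median of 1.83 and Pcsk9 (3.27), Insig1 (2.53) and Idi1 (2.51) among them. Camera called them at adjusted p = 6.29e-48, and at adjusted p = 9.34e-05 with an estimated correlation. Integrated stress response genes were lower in 20 of 22 cases and higher in 2, with Trib3 at 24.8 ± 0.801 against 143 ± 7.81 CPM, Cth (-2.86), Nupr1 (-2.68) and the amino acid transporter Slc7a5 (-2.39). Their adjusted p was 8.22e-26, with adjusted p = 0.00579 with an estimated correlation. Cell cycle genes were lower in 29 of 38 and higher in 1 (the cyclins Ccnb2 -2.14 and Ccna2 -1.82, the kinase Plk1 -1.79; adjusted p = 2.49e-09, and adjusted p = 0.00471 with an estimated correlation). Mki67 stood at 31.7 ± 0.686 CPM against 60.5 ± 10.1 in WT. Macrophage and myeloid markers were lower in 23 of 26 and higher in 1, with C1qb (-4.52) and Fcgr1 (-3.97; adjusted p = 1.96e-12, and adjusted p = 0.0104 with an estimated correlation). The mitochondrial share of counts was 1.21 to 1.27% in these libraries, again below the 2.14 to 2.28% of WT.

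Pigmentation genes were higher in 11 of 14 cases and lower in 1 in Bptf libraries. The melanosome exchanger Slc24a5 (5.00), Gpnmb (2.14), the copper transporter Atp7a (1.78) and Myo5a (1.32) were higher (list adjusted p = 0.000112, and adjusted p = 0.0696 with an estimated correlation). Higher than in WT were also Sox10 at 148 ± 2.44 CPM (0.85 ± 0.08, edgeR adjusted p = 8.32e-07), Mitf at 11.5 ± 0.947 (0.46 ± 0.10, adjusted p = 0.00116) and Ngfr at 375 ± 8.39 (1.95). Erbb3 (0.97), Pax3 (0.82), Ednrb (0.82), Axl (0.44) and Cdkn1a (0.30) were higher and Sox9 lower (-0.47). Mlana was higher (1.65, adjusted p = 0.0173, from 10 to 34 counts), a call lost without Bptf replicate 3 (0.105) or WT replicate 3 (0.0721). Pmel was higher (0.71, adjusted p = 0.0277), a call lost with DESeq2 (0.0844) and without Bptf replicate 2 (0.0786), Bptf replicate 3 (0.0658) or WT replicate 1 (0.083). Kit (0.30) did not pass. Melanocyte and neural crest regulators were higher in 15 of 23 and lower in 4 (Sox6 4.49-fold, Lef1 1.80, Msx1 -1.08; adjusted p = 0.0332, and adjusted p = 0.239 with an estimated correlation). Mitf targets outside pigmentation were higher in 9 of 22 and lower in 4 (Rragd 4.33, Scd2 2.11; adjusted p = 0.0486, and adjusted p = 0.239 with an estimated correlation).

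MAPK output genes were higher in 17 of 20 cases and lower in 2 in Bptf libraries (Egr1 2.78, Fos 2.08, Dusp4 1.55; adjusted p = 1.1e-08, and adjusted p = 0.0863 with an estimated correlation). Lysosome genes were higher in 25 of 29 and lower in 1 (Gla 1.64, Ctsd 1.08, Ctss -1.98; adjusted p = 1.52e-06, and adjusted p = 0.183 with an estimated correlation). Interferon genes were lower in 18 of 25 and higher in 4 (19 and 4 adjusted over the list alone; Isg15 -2.07, Oas2 -1.82, Irf7 -1.39; adjusted p = 1.16e-05, and adjusted p = 0.0696 with an estimated correlation). Fibroblast genes were lower in 18 of 25 and higher in 4 (Col3a1 -1.63, Col1a1 -1.56, Lox -1.45; adjusted p = 8.36e-07, and adjusted p = 0.0863 with an estimated correlation). Oxidative phosphorylation genes were lower in 16 of 27 and higher in 3 (18 and 3 adjusted over the list alone), with the cytochrome oxidase subunit genes Cox5b (4.01-fold), Cox7c (-1.53) and Cox5a (-1.34) among them. This list had adjusted p = 0.0047, and adjusted p = 0.569 with an estimated correlation. The lists not called included NURF and ISWI complexes (0.0712, 10 higher and 1 lower of 13, with Smarca1 at 1.13 and Rsf1 at 0.59) and glial (0.527, 9 higher and 6 lower of 19, with Egr2 at 2.93, Cdh19 at 1.61 and Gfap at -1.91). Also not called were invasive state (0.578, 11 higher and 10 lower of 29, with Nt5e at 2.22 and Il6 at -2.40) and smooth muscle and pericyte (0.384, 4 higher and 6 lower of 13, or 4 and 7 adjusted over the list alone, with Notch3 at 0.99 and Cnn1 at -1.08).

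In all, 4711 genes were higher and 4864 lower in Bptf libraries than in WT (65.6% of those tested), 1008 and 1164 of them over 2-fold, with groups apart in 71.1% of genes against 10% by chance. The other lists not called were p53 targets (adjusted p = 0.279), class I antigen presentation (0.283), secreted inflammatory factors (0.527, 10 higher and 10 lower of 24, with Ccl20 at -4.25 and Ptgs2 at 2.45), hypoxia and glycolysis (0.196), unfolded protein response (0.595), BAF and PBAF complex (0.89), T and NK cell (0.965), mast cell (0.196), endothelial (0.99), keratinocyte and epidermis (0.0998), hair follicle (0.283), adipocyte (0.196) and skeletal muscle (0.782). Median, mean and test differed in sign for the inflammatory, T and NK cell and endothelial lists. The B and plasma cell and erythroid lists had fewer than 3 tested members in both tables.

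Smarca4 and Bptf libraries shared part of their differences from the same WT samples. Of the 4850 genes higher in Smarca4 libraries, 2546 (52.5%) were also higher in Bptf libraries, against 1567 for independent sets, and of the 4934 lower, 2526 (51.2%) were also lower, against 1645. A further 797 and 930 genes went opposite ways. Besides the Y-linked genes and Xist, Akr1c18 (5.35 and 6.10) and the X-linked gene Mtap7d2 (6.41 and 5.28) were among the shared increases, and C1qc, Cdkn1c (-5.53 and -5.81), the keratin Krt7 (-5.78 and -3.72), the chemokine Pf4 (-5.36 and -3.70) and the morphogen Bmp4 (-4.97 and -3.65) among the shared decreases. With unchanged groups and shared controls, 20 simulations gave a correlation across genes of 0.53 against the observed 0.58, a covariance of 0.0224 against 0.689 (difference 0.667) and the same sign in 67.2% of genes against 64.5%. Part of the excess over independent sets may come from the shared WT samples. The simulations drew all groups at the WT mean, so they cover only counting error and the spread between replicates. WT also differed from both other groups in Xist and Y-linked genes. A different origin of the WT cells could give shared differences without a deletion, and how much it gives was not tested.

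Tested directly, Smarca4 and Bptf libraries differed in 10 gene lists, of which integrated stress response, cell cycle, smooth muscle, interferon and glial genes were called also with an estimated correlation. All 22 integrated stress response genes were higher in Smarca4 than in Bptf libraries (median 2.04; Trib3 3.53, Chac1 3.46, Atf3 3.30, Ddit3 2.91; adjusted p = 1.12e-38, and adjusted p = 0.00531 with an estimated correlation). Cell cycle genes were higher in 26 of 38 and lower in 9 (27 and 9 adjusted over the list alone; Cdt1 2.65, Ccnb2 2.32, Plk1 1.61; adjusted p = 0.000604, and adjusted p = 0.0367 with an estimated correlation). Smooth muscle genes (12 of 13 lower, 1 higher; Lmod1 -5.66, Mylk -5.15, Acta2 -3.46), interferon genes (20 of 25 lower, 2 higher; Oas2 -3.78, Gbp2 -3.66) and glial genes (11 of 19 lower, 3 higher; Scn7a -3.89, Mal -2.51) were lower at adjusted p 1.55e-18, 4.72e-15 and 0.000329. These held with an estimated correlation, at adjusted p = 0.0245, adjusted p = 0.0245 and adjusted p = 0.0341. Invasive-state genes were lower in 20 of 29 and higher in 8 (Thbs1 -5.63, Ctgf -5.22, Ankrd1 -3.99, Inhba -3.98; adjusted p = 1.46e-13, and adjusted p = 0.0754 with an estimated correlation). Macrophage markers were lower in 19 of 26 (Mpeg1 -2.23, Lyz2 -1.74; median -2.21, or -2.07 with groups at 0 placed at the floor; adjusted p = 0.00873, and adjusted p = 0.337 with an estimated correlation). Fibroblast genes were lower in 17 of 25 and higher in 4 (18 and 4 adjusted over the list alone; Lum -2.52, Col3a1 -1.59, Twist2 1.99; adjusted p = 0.00191, and adjusted p = 0.298 with an estimated correlation). Class I genes were lower in 13 of 14 (Psmb8 -1.59, H2-D1 -1.06; adjusted p = 0.00257, and adjusted p = 0.298 with an estimated correlation), and cholesterol genes in 19 of 24 with 1 higher (Hsd17b7 -1.42; adjusted p = 0.0148, and adjusted p = 0.0866 with an estimated correlation).

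Of the genes named in every comparison, Sox9 (1.47), Ednrb (1.23), Pax3 (0.99), Mki67 (0.67) and Cdkn1a (0.24) were higher in Smarca4 than in Bptf libraries, and Pmel (-0.96), Bptf (-0.86), Axl (-0.68), Erbb3 (-0.51), Smarca4 (-0.47) and Ngfr (-0.44) lower, as was the pigmentation gene Slc24a5 (-3.12). Kit (0.57, adjusted p = 0.296) did not pass, nor did Mlana (0.68, adjusted p = 0.121), which passed without Bptf replicate 3 (1.1, adjusted p = 0.0496). With no count filter, Tyr was higher in Smarca4 libraries (43 against 5 counts, 2.66, adjusted p = 0.000764), and Tyrp1, Dct and Zeb1 did not pass. Sox10 (0.21, adjusted p = 0.0281) lost its call when any Bptf replicate was left out (0.0929, 0.0715 and 0.0632), and without Smarca4 replicate 1 (0.126) or 2 (0.104). Mitf (0.28, adjusted p = 0.0163) lost it without Smarca4 replicate 3 (0.0939) or Bptf replicate 3 (0.101). In total 5195 genes were higher and 5126 lower (70.8% of those tested; 1226 and 1984 over 2-fold), with groups apart in 79.3% of genes against 10% by chance. With library totals only, the median of all genes shifted by 0.156 and 61.9% of called genes were higher against 50.3% with TMM.

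Among genes lower in both a knockdown and a deletion, and among those higher in both, siSox10 and Smarca4 had the highest odds ratio. Among 13694 genes tested in both tables, 1493 were lower with siSox10 and in Smarca4 libraries, against 793 for independent sets (odds ratio 4.66, Fisher's exact p = 6.37e-236, 1.02e-234 after Benjamini-Hochberg over 16 tests), and 1327 were higher in both against 784 (odds ratio 3.27). The opposite pairs held 474 and 381 genes, against 794 and 783. For siMitf and Smarca4, 1084 were lower in both against 578 (odds ratio 4.2) and 895 higher against 558 (odds ratio 2.64). Odds ratios with Bptf libraries were lower. Genes lower in both numbered 1030 with siSox10 against 787 (odds ratio 1.71) and 643 with siMitf against 574 (odds ratio 1.23), and genes higher in both 1110 against 769 and 738 against 548. Genes lower with siMitf and higher in Bptf libraries numbered 592 against 560 and did not pass (adjusted p = 0.0771). Shared counts moved with scaling. With library totals only, siSox10 and Smarca4 shared 2512 higher and 960 lower genes, and siMitf and Smarca4 1854 and 692. In that setting siSox10 and Bptf shared 1756 higher and 679 lower, and siMitf and Bptf 1247 higher. Odds ratios were computed with TMM only. Across genes, the correlation of log2 fold changes ran from 0.15 (siMitf and Bptf) to 0.37 (siSox10 and Smarca4), and genes are not independent replicates in these tests. The deletion side of each overlap is a comparison with WT, in which the deletion and the origin of the cells cannot be told apart. Sox10 and Mitf were themselves higher in Smarca4 libraries (172 and 13.9 CPM) than in WT (82.4 and 8.32 CPM). The overlaps therefore do not show a programme shared by these factors.

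The authors' deposited lists of changed genes hold 198 higher and 190 lower genes for siMitf, 376 and 424 for siSox10, 1341 and 2293 for Smarca4, and 1056 and 1245 for Bptf. They hold genes past an absolute log2 fold change of 1 at an adjusted p under 0.05. The lower lists of Smarca4 and Bptf each hold 1 gene without an adjusted p. Calls made here had no minimum fold and came from the same counts, so close agreement on the listed genes was likely beforehand. Of those tested here, 191 of 193, 186 of 186, 354 of 354, 400 of 402, 1233 of 1234, 2012 of 2012, 989 of 989 and 1105 of 1106 were called the same way by edgeR, in that order. None (0) was called the opposite way by edgeR, in comparisons where 4941, 6006, 10188 and 10039 genes had an unadjusted p under 0.05.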

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

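Of the 685 named results, none that passed the test reversed its direction under an alternative. Values near 0 that did not pass could change sign, such as Cdkn1a with siMitf (-0.07) and siSox10 (-0.08), each 0.02 with library totals only. So did medians of lists that were not called, such as Mitf targets with siMitf (-0.04, or 0.05 with library totals only). The cause of the changes below was not tested. Each of RLE size factors, the replicate block, only the 2 compared groups and autosomes only left 44 of 44 counts within 1.5 times of the value given, and DESeq2 left 32 of 32. The sample numbers do not pair across groups (correlations -0.22 to 0.05), so the replicate block is given only here. For named genes, DESeq2 changed 9 calls, library totals 16 lost and 4 gained, no count filter 3, only 2 groups 9 and the block 14. Leaving out 1 library lost the most named calls without siSox10 replicate 2 (34), siMitf replicate 2 (28) and siC replicate 3 (27).

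Library totals only moved 13 of 44 counts: siMitf 2909 higher and 1109 lower, siSox10 3768 higher, siMitf and siSox10 shared 2364 higher and 828 lower, siMitf and Smarca4 shared 1854 and 692, siMitf and Bptf shared 1247 higher, siSox10 and Smarca4 shared 2512 and 960, siSox10 and Bptf shared 1756 and 679, and 3 lists lower with siSox10. No count filter moved 2 of 44: 799 genes higher in siSox10 against siMitf, and 6 lists lower with siMitf. A mean count of at least 50 moved 4: of the authors' deposited lists, 110 higher (siMitf), 212 higher and 262 lower (siSox10) and 679 lower (Bptf) were called the same way.

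An absolute log2 fold change over 1 moved all 24 counts, to 219 higher and 210 lower (siMitf), 394 and 439 (siSox10), 33 and 103 (siSox10 against siMitf), 1278 and 2040 (Smarca4), 1008 and 1164 (Bptf), and 1226 and 1984 (Smarca4 against Bptf). Shared genes became 177 and 175 (siMitf and siSox10), 490 and 598 (Smarca4 and Bptf), 107 and 140 (siMitf and Smarca4), 86 and 65 (siMitf and Bptf), 185 and 241 (siSox10 and Smarca4), and 131 and 106 (siSox10 and Bptf). An adjusted p under 0.01 moved 5 of 12, to 953 and 997 (siMitf), 1558 higher (siSox10), and 231 and 285 (siSox10 against siMitf). The edgeR test against a fold of 1.5, chosen after the data were seen, gave 1725 and 2379 (Smarca4), 1356 and 1437 (Bptf), and 1792 and 2402 (Smarca4 against Bptf).

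Lists called higher and lower were 7 and 3 (siMitf), 7 and 5 (siSox10), 4 and 4 (siSox10 against siMitf), 6 and 8 (Smarca4), 6 and 6 (Bptf), and 2 and 8 (Smarca4 against Bptf). With an estimated correlation they were 0 and 1, 0 and 2, 0 and 0, 1 and 2, and 1 and 3 in that order, and 3 lower for Smarca4 against Bptf. With fry, 6 were lower (siMitf), 12 higher (siSox10), 11 and 17 (Smarca4), 11 and 15 (Bptf), and 7 and 18 (Smarca4 against Bptf). Leaving out 1 library moved only siSox10 against siMitf, with 215 to 615 higher (323 without siMitf replicate 2, 215 without siSox10 replicate 2) and 250 to 703 lower (404 without siMitf replicate 1, 250 without siSox10 replicate 2).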

Other observations

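The biological process tests in this paragraph were chosen after the data were examined. They covered 423 terms of 15 to 200 genes in the knockdown table and 431 in the deletion table. Translation genes were lower in 147 of 192 cases and higher in 5 in Bptf libraries (median log2 fold change -0.62, camera adjusted p = 6.75e-08, and adjusted p = 0.817 with an estimated correlation). Homophilic cell adhesion genes, a class that holds the cadherins, were higher in 45 of 70 and lower in 6 there (adjusted p = 0.000149, and adjusted p = 0.78 with an estimated correlation). Collagen fibril organization genes were lower in 13 of 19 and higher in 3 in Smarca4 libraries (1.39e-05, and adjusted p = 0.48 with an estimated correlation), and lower in 15 and higher in 3 in Bptf libraries (1.51e-06, and adjusted p = 0.567 with an estimated correlation). Glutathione metabolic genes were higher in 16 of 25 and lower in 6 in Smarca4 libraries (6.69e-05, and adjusted p = 0.48 with an estimated correlation), and higher in 17 and lower in 6 in Bptf libraries (0.00285, and adjusted p = 0.567 with an estimated correlation). Wound healing genes were lower in 19 of 29 and higher in 4 in Smarca4 libraries (1.09e-05, and adjusted p = 0.193 with an estimated correlation). With siSox10, genes of receptor tyrosine kinase signaling were lower in 15 of 27 and higher in 3 (0.000487, and adjusted p = 0.653 with an estimated correlation). Only cholesterol biosynthetic process in Bptf libraries (16 of 20 higher, 3 lower, median 1.75, 4.66e-24) held, at adjusted p = 0.0102 with an estimated correlation.

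Genes without a count in a group, also chosen after the values were seen, extend the picture of the deletion table. Smarca4 libraries had no count of the mast cell tryptase gene Tpsb2 (121 in WT) or of the myeloid genes Ms4a6c (105) and Aif1 (104), and Bptf libraries none of Tpsb2 and the bone morphogenetic gene Bmp3 (64). WT had none of the myostatin gene Mstn (88 in Smarca4 libraries) or of the organic cation transporter gene Slc22a3 (242). All 7 tested protein genes of the mitochondrial genome were lower in Smarca4 libraries (median log2 fold change -1.05, from -1.71 to -0.95) and in Bptf libraries (-0.80, from -1.28 to -0.56), against a median of -0.06 with siMitf and -0.03 with siSox10.

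Of the tests weighed from here on, those on shared controls, on a gain of the region and on other splits were planned before the results were seen, and the other tests were chosen after. Most tested genes were called in each comparison of the deletion table. Sex chromosome genes do not account for this, as 96.5% of the calls of Smarca4 against WT were autosomal, and 67.1% of X-linked and 67.1% of autosomal genes were called. Small differences between close replicates cannot account for all of it, since 41.9% of those calls passed the test against a fold of 1.5. All 5 of Xist and 4 Y-linked genes were called in both comparisons with WT. Ddx3y had 5 counts in WT against 83.0 and 91.7 CPM in Smarca4 and Bptf libraries. Xist stood at 468 CPM in WT against 0.201 and 0.364 CPM. A deletion in cells of 1 animal cannot switch on Y-linked genes, so these values argue for WT and floxed cells from different animals. How many of the other calls come from the origin of the cells stays open. Control and floxed cells of the same line, with and without 4-OHT, would test this.

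Many genes were called the same way with siMitf and siSox10. Shared siC libraries can give at most part of it, as the observed covariance was 9.8 times the highest simulated one. Lower Mitf mRNA with both siRNAs does not account for it, because the log2 fold change of Mitf with siSox10 was 0.50. Mitf protein was not measured in these data. A response to any targeting siRNA against the control siRNA could give the same genes: only 14% of the 2633 shared calls differed between siSox10 and siMitf, a share that also depends on the power of that comparison. A second siRNA per target, which these groups lack, would test this hypothesis.

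Bptf mRNA was higher in the libraries labelled Bptf than in WT (log2 fold change 0.96). A gain of most of the region does not account for it, since the median log2 fold change of 102 genes within 5 Mb was 0.05 (95% bootstrap interval -0.05 to 0.17). Of these genes, 33 were called higher and 27 lower. A median over the window cannot detect a gain limited to Bptf and a few neighbours. Exchanged labels of Smarca4 and Bptf libraries would place a lower Smarca4 in the libraries labelled Bptf, where its log2 fold change was 0.25. This does not settle the labels, because the tables do not show whether deletion lowers the gene-level count. Reads over the floxed exons, which gene counts do not hold, would test it.

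In each comparison the 6 samples allow 10 splits into groups of 3, too few for a share under 0.05. All splits except the real split mix libraries of both groups. A difference between the groups then adds to the spread within each mixed set and works against calls. The counts of the mixed splits therefore do not show how many calls arise without a difference, and no conclusion is drawn from them. The real split was the only 1 of 10 to reach its number of calls (3386 for siMitf, 4716 for siSox10, 1149 for siSox10 against siMitf, 9784 for Smarca4, 9575 for Bptf and 10321 for Smarca4 against Bptf), and the other splits gave at most 0 calls with edgeR. At an unadjusted p under 0.05, the other splits held 178 to 774, 135 to 650, 191 to 2303, 66 to 669, 94 to 210 and 48 to 60 genes in that order.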
